A study of Mus musculus with 12 samples.

How the data were processed

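The values came from RNA sequencing of mouse urogenital sinus (UGS) at embryonic day 18.5, in 12 libraries that form 4 groups of 3: wild type females, wild type males, mutant females and mutant males. Per the labels, the UGS was separated from the bladder and kept the proximal urethra and, in females, the vagina. RNA of a quality number (RIN) above 9.5 was made into strand-specific single-end libraries from ribosomal-RNA-depleted total RNA, per the labels. The mutant genotype is Inv(Itga6-nsi)d11lac, which names an inversion with an end at Itga6 and an end called nsi, and an allele called d11lac.

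The deposited table holds FPKM values (fragments of a gene, scaled to its length and to the mapped fragments of the library), per the file headers, for 56495 genes in the 12 libraries, and 0 columns of other samples. Per the submitters' processing notes, the authors used cutadapt 4.1, STAR 2.7.10a, Cufflinks 2.2.1 and bedtools 2.30.0 and the genome builds mm39 and mm10, with no order or role stated. The table gave 2.74% of the genes found in the GENCODE M21 annotation of GRCm38 the same end position, so its positions are given here as mm39. The lengths of 46732 genes matched that annotation with starts counted from 0, and of 148 with starts counted from 1. The starts printed here are therefore those of the table plus 1. The annotation behind the FPKM, its masked genes and the strand setting were not stated. All 36 mitochondrial genes stood at 0 in every library. An exact 0 in such a table can be a failed estimate and is written as listed at 0.

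FPKM give no read counts, so depth was recovered only in relative terms. Among genes under 0.05 FPKM, the values of a library lie at steps of 1 read for each gene length, and the ratio of these steps between libraries was read from the fullest bin of 0.02 on the log2 scale. Between 79.3% and 81.0% of the low values lay within 0.03 of the ratios that 1 to 4 reads give. No total count, counting interval or detection floor was computed.

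Each library was divided by its median ratio to the geometric mean over the 11897 genes with at least 1 FPKM in all 12 libraries, with divisors from 0.748 to 1.131. Genes with at least 1 FPKM in at least 3 libraries were tested, which kept 13904 genes, and values were taken as log2 of the scaled FPKM plus 0.5. Fold changes on this scale understate genes with low values. The fit used limma 3.58.1 in R 4.3.3 with statmod 1.5.0, a mean for each of the 4 groups, an intensity trend in the prior variance and two-sided moderated tests. Genes with a Benjamini-Hochberg adjusted p under 0.05 over the 13904 genes are said to be called. The 6 comparisons were mutant versus wild type in males, in females and over both sexes, the difference of the mutant effect between sexes, and male versus female in wild type and in mutant. The labels do not say whether the replicates of a group came from separate embryos, so the p-values measure the spread between these libraries.

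Gene lists were tested with the camera test of limma at a preset correlation of 0.01 and again with an estimated correlation, over all lists with at least 4 members past the filter, and adjusted within a comparison. The 26 lists tested covered the HoxD cluster, posterior HoxD genes, genes between Itga6 and Evx2, other posterior Hox genes, anterior Hox genes, prostate bud and androgen genes, Müllerian duct and vagina, Wolffian duct and seminal vesicle, hedgehog, Wnt, and BMP and FGF signalling, urothelium, smooth muscle, skeletal muscle, neural cells, mesenchyme, cartilage, blood, immune cells, endothelium, epidermis, adipose tissue, proliferation, immediate early genes, extracellular matrix and mitochondrial oxidative phosphorylation. Lists for intestine, gonad and adrenal, and kidney had fewer than 4 members past the filter. Some genes stand on several lists, so the calls of such lists are not independent. Members called were counted over all genes tested and adjusted over the list alone. Pearson and Spearman correlations of the sex differences in the 2 genotypes ran across genes, which are not independent replicates, so they carry no p-value.

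Named genes followed a rule. It took every tested member of the HoxD cluster list, with the genes between Itga6 and Evx2 as a summary, and the 10 largest rises and 10 largest falls in males, in females, over both sexes and between the sexes in wild type. These came from called genes whose libraries did not overlap between the groups and whose higher group mean was at least 2 scaled FPKM, leaving out unnamed gene models, pseudogenes and short RNAs. It also took the 4 members that moved most in the direction of each called list, Xist and 4 genes of the Y chromosome as a check of the labels, and the 5 smallest p-values where no gene passed. The comparisons, lists, filter, pseudocount, scaling, rule and most alternatives were fixed before the data were examined.

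The alternatives were pseudocounts of 0.1 and 1, no filter, a filter at 5 FPKM in at least 3 libraries, no scaling, quantile normalization, scaling to the sum of each library, the replicate number as a block, only the groups compared, a robust prior without a trend, library weights, an estimated list correlation and leaving out each library in turn. Chosen after seeing the data were protein-coding genes only, a correction for GC content and transcript length, the correction with the replicate block, and leaving out each library for the correlation of sex differences. The correction removed a loess trend of each library's deviation from the gene mean on GC content and then on log2 length. Both came from the longest transcript of the gene in GENCODE M21, matched by gene identifier, for 13735 of the 13904 genes (98.8%). Lists of replication-dependent histones, cytosolic ribosomal proteins, cholesterol synthesis and genes imprinted with Rtl1 were also chosen after values had been seen and carry no place among the 26.

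The fit was tested on simulated data with 200 changed genes in mutant males. It recovered 41.8% of changes of 0.5 on the log2 scale, 80.6% of changes of 1 and 100% of changes of 2, with 10 other genes called. With no change simulated, 0 of 13666 genes were called by limma in each of the 6 comparisons, with 646 to 690 genes at an unadjusted p under 0.05. A simulated GC trend in mutants gave 1163 other calls, and 8 after the correction. A shifted list was called by camera at an adjusted p of 2.67e-17 with 0 other lists called. The simulated genes varied independently, so this does not test false calls of lists whose members vary together. In the data the estimated correlation was 0.552 for skeletal muscle and 0.709 for blood genes. Splits of the libraries into other groups of the same sizes were counted as well. Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6. Sequence reads and their alignment were not analysed here.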

Results

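Gene expression was measured by RNA sequencing in the urogenital sinus of late fetal mice, the tissue around the proximal urethra from which the prostate buds in males. In females the samples also kept the vagina, per the labels. The 12 libraries formed 4 groups of 3: wild type females, wild type males, and females and males of the genotype Inv(Itga6-nsi)d11lac, called mutant here. By its name, the mutant chromosome carries an inversion with an end at Itga6, on the same chromosome as the HoxD cluster of body-axis and genital patterning genes. The labels did not give the position of the other end, called nsi, or describe the d11lac allele. Relative sequencing depth was 0.81 to 1 in the 6 wild type libraries and 0.582 to 0.717 in the 6 mutant libraries, so the groups did not overlap in depth. FPKM sums ranged from 276713 to 401093. The small nuclear RNA Rn7sk took 12.2% to 14.9% of that sum in wild type male 1, mutant male 1 and mutant male 3, and was listed at 0 in the other 9 libraries.

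The sex labels matched the libraries. Xist, the RNA that silences an X chromosome in females, was at 5.51 to 10.5 scaled FPKM in the 6 female libraries and at 0 to 0.242 in the 6 male libraries. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had means of 3.79 to 15.2 scaled FPKM in wild type males and 4.01 to 8.56 in mutant males, and at most 0.0274 in either female group (n = 3 libraries per group). Components 1 and 2 of a principal component analysis held 35.2% and 19.8% of the variance. Along component 1 the mutant libraries lay lower than the wild type libraries of the same sex, at -47.5 to -24.4 against 2.5 to 10 in females and at -7.0 to 7.4 against 26.5 to 34.1 in males.

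The first question was how HoxD genes fared on the inverted chromosome. Hoxd12 and Hoxd13, the genes at the end of the cluster that acts last and most posteriorly, fell about equally in both sexes. Hoxd13 (ENSMUSG00000001819, chromosome 2, 74498654 to 74501943 in mm39) went from 17.1 ± 1.88 scaled FPKM in wild type males to 4.77 ± 1.26 in mutant males and from 18 ± 2.23 to 4.50 ± 1.26 in females (SD, n = 3 libraries). Hoxd12 (ENSMUSG00000001823, 74505357 to 74508049) went from 8.25 ± 1.07 to 1.63 ± 0.349 in males and from 8.77 ± 1.44 to 2.01 ± 0.888 in females. Their neighbour Hoxd11 (ENSMUSG00000042499, 74512667 to 74514512) moved the other way, from 2.83 ± 0.288 to 7.38 ± 1.37 in males and from 3.13 ± 0.152 to 8.02 ± 3.39 in females. Hoxd10 (ENSMUSG00000050368, 74522268 to 74525449) fell from 4.02 ± 0.259 to 2.26 ± 0.41 in males and from 4.13 ± 0.161 to 1.62 ± 0.366 in females.

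**Figure D1:**
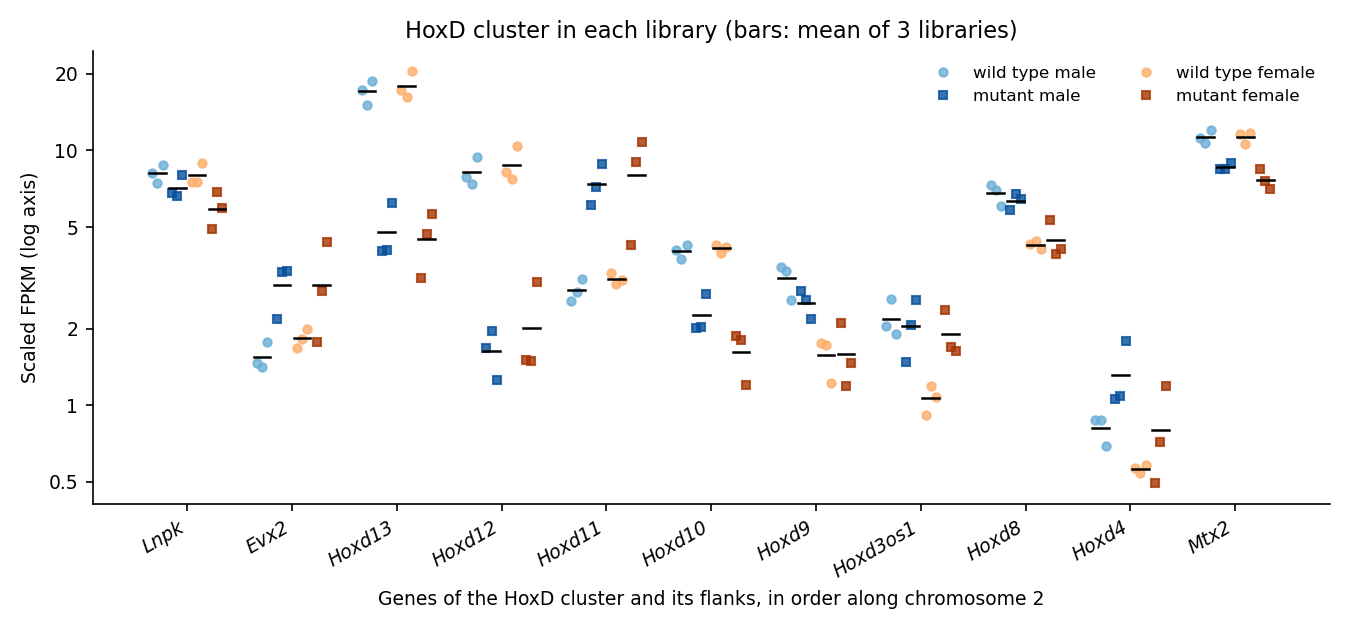
Scaled FPKM of the 11 tested genes of the HoxD cluster list in each of the 12 libraries, on a log axis, with points for libraries and bars at the mean of 3 libraries per group. Hoxd12 and Hoxd13 lie lower and Hoxd11 higher in the mutant libraries of both sexes, with Hoxd13 at 17.1 and 4.77 in wild type and mutant males.

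Over both sexes, the limma log2 fold changes were -1.99 for Hoxd12 (SE 0.15, Benjamini-Hochberg adjusted p = 3.69e-05) and -1.84 for Hoxd13 (SE 0.14, adjusted p = 3.69e-05). Hoxd10 changed by -0.93 (SE 0.10, adjusted p = 1e-04) and Hoxd11 by 1.18 (SE 0.18, adjusted p = 0.000546). In males alone the limma adjusted p-values were 0.0013, 0.00132, 0.00708 and 0.00889 for Hoxd12, Hoxd13, Hoxd10 and Hoxd11, and in females 0.000546, 0.00038, 0.000676 and 0.00829. Evx2, the homeobox gene beside Hoxd13, rose by 0.62 over both sexes (SE 0.17, adjusted p = 0.0129), with 0.74 in males and 0.51 in females not called (adjusted p = 0.0505 and 0.133). Mtx2, a mitochondrial import gene at the other end of the cluster, fell by 0.45 over both sexes (SE 0.06, adjusted p = 0.000202) and in each sex. Lnpk, an endoplasmic reticulum gene beyond Evx2, had values of -0.30 over both sexes (adjusted p = 0.0192), -0.41 in females (adjusted p = 0.0292) and -0.18 in males (adjusted p = 0.33). The antisense RNA Hoxd3os1 rose in females by 0.61 (adjusted p = 0.0314), with -0.10 in males (adjusted p = 0.754). Over both sexes Hoxd4, Hoxd8 and Hoxd9 stood at 0.35, -0.02 and -0.13, and 0 of these 3 passed in any of the 3 genotype comparisons, with unadjusted limma p from 0.0391 to 0.996.

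As a group, 1 of the 11 tested HoxD cluster genes rose and 4 fell in males, 2 rose and 5 fell in females, and 2 rose and 5 fell over both sexes. Of all genes tested, 20.3%, 28% and 40.6% were called in these 3 comparisons. Adjusted over the list alone, 2 rose and 4 fell in males, 2 and 5 in females, and 2 and 5 over both sexes, and camera called the list in none of the 3 comparisons (adjusted p = 0.137, 0.322 and 0.215). After a correction for GC content and transcript length, chosen after seeing the data, the values over both sexes were -2.10 for Hoxd12, -1.73 for Hoxd13, -0.76 for Hoxd10 and 1.49 for Hoxd11. The correction reversed Lnpk over both sexes, from called lower at -0.30 to called higher at 0.29 (limma adjusted p = 0.0224), and turned it to 0.24 in females (adjusted p = 0.169). It brought Mtx2 to -0.2 over both sexes and -0.26 in females, both still called, and to -0.15 in males, not called (limma adjusted p = 0.0188, 0.0477 and 0.252), and lowered Hoxd9 to -0.40, which then passed. The calls of Hoxd10, Hoxd11, Hoxd12 and Hoxd13 held without any 1 of the 12 libraries. Lnpk in females lost its call without any 1 of mutant females 1 and 3 and wild type females 1, 2 and 3 (limma adjusted p of up to 0.11). Hoxd3os1 in females lost its call without mutant female 1 or wild type female 1, 2 or 3 (limma adjusted p of up to 0.106).

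Among 16 tested genes between Itga6 and Evx2, 7 fell and 1 rose over both sexes, 6 fell and 0 rose in males, and 5 fell and 0 rose in females; adjusted over the list alone, 8, 6 and 5 fell and 1, 1 and 0 rose. The transcription factor Sp3 fell by 0.60 over both sexes (SE 0.05, limma adjusted p = 4.28e-05) and the ATPase Ola1 by 0.47 (SE 0.06, adjusted p = 0.000221). Rapgef4, a cAMP-responsive exchange factor, fell by 0.56 and Gpr155 by 0.42 (adjusted p = 0.00308 and 0.00469). Itga6, the integrin gene at the named end of the inversion, had a value of -0.24 (SE 0.09, adjusted p = 0.051) and was not called. The list was not called by camera (adjusted p = 0.108 in males, 0.126 in females and 0.0916 over both sexes). For scale, 20.3% of all genes tested were called in males, 28% in females and 40.6% over both sexes. After the GC and length correction, 4 of the 16 fell and 3 rose over both sexes, 1 fell and 0 rose in males and 0 were called in females. The medians were then -0.16 over both sexes, -0.01 in males and -0.03 in females. Posterior Hox genes of the other clusters did not move with Hoxd12 and Hoxd13: 4 of 9 tested members rose and 0 fell over both sexes, with 4 adjusted over the list alone and a median of 0.16 (camera adjusted p = 0.14). Among 7 tested anterior Hox genes 4 rose and 0 fell, also 4 adjusted over the list alone (median 0.36, adjusted p = 0.14). With the FPKM as deposited none of either list was called. After the GC and length correction 2 of the 9 posterior and 0 of the 7 anterior genes were called higher and 0 lower, at medians of 0.12 and 0.21.

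In males, Ckm and Myoz1 were among the genes that fell most and Rtl1, Ramp3, H3c10, Wnt16 and Krt5 among those that rose most. Ckm, the creatine kinase of muscle, fell from 43.0 ± 6.91 to 9.92 ± 0.691 scaled FPKM (SD, n = 3), a log2 fold change of -2.05 (SE 0.23, limma adjusted p = 0.00132), and the muscle Z-disc gene Myoz1 fell by 1.54 (SE 0.32, adjusted p = 0.00896). Rtl1, an imprinted gene derived from a retrotransposon, rose from 2.14 ± 0.129 to 8.90 ± 0.656 (1.83, SE 0.11, adjusted p = 4.61e-05). Ramp3, a partner of the adrenomedullin receptor, rose by 1.64 (SE 0.22, adjusted p = 0.00224), and the histone gene H3c10 by 1.87 (SE 0.19, adjusted p = 0.00113). The signal Wnt16 rose by 1.66 and Krt5, a keratin of basal epithelial cells, by 1.45 (adjusted p = 0.0121 and 0.00909).

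The haemoglobin gene Hba-a2 rose most, by 4.44 (SE 1.00, limma adjusted p = 0.012), from 18 to 60.2 scaled FPKM in the 3 wild type males to 557 to 1707 in the 3 mutant males. Other large rises were 1.52 for Isg20, 1.48 for Ndufa4l2, 1.40 for C1qtnf9 and 1.32 for Ppp1r1b. Large falls besides Hoxd12, Hoxd13, Ckm and Myoz1 were -2.21 for Tmsb15b1, -1.64 for Arhgap36, an activator of hedgehog signalling, -1.5 for Klhl4, -1.39 for Atp1b4, -1.36 for Prr32 and -1.33 for Aspn, a matrix proteoglycan. Of the Y-linked genes, Ddx3y, Eif2s3y and Uty fell by 0.79, 1.10 and 1.06 (limma adjusted p = 0.00224, 0.00204 and 0.00741) and Kdm5d had a value of 0.09 (adjusted p = 0.731). Of 13904 genes, 1202 rose and 1618 fell (limma adjusted p under 0.05), 31 and 101 of them by at least 2-fold. With the FPKM as deposited, which shifted the median of all genes to -0.14, 121 rose and 1229 fell, and with scaling to the library sums 444 rose and 1992 fell. The total of 2820 became 1240 without mutant male 1, 1649 without mutant male 2, 1247 without wild type male 1 and 1817 without wild type male 2, and 556 after the GC and length correction.

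Skeletal muscle genes were the list that moved most clearly in males. Of its 24 tested members 13 fell and 0 rose, with 14 adjusted over the list alone, at a median of -0.74. Its camera adjusted p was 5.72e-06 (4.05e-12 to 0.494 over its alternatives), and adjusted p = 0.494 with an estimated correlation. After Ckm, the contractile genes Tnni2, Tnnt3 and Tnnc2 fell by 1.25, 1.19 and 1.13 (limma adjusted p = 0.00333, 0.00547 and 0.00396). Of 20 mitochondrial oxidative phosphorylation genes 6 fell and 0 rose, with 7 adjusted over the list alone. Camera gave this list an adjusted p of 0.00326 (3.89e-06 to 0.494 over its alternatives), and adjusted p = 0.494 with an estimated correlation. These were small changes, with Ndufa4 at -0.49, Cycs at -0.41, Ndufa1 at -0.35 and Ndufb5 at -0.34 (limma adjusted p = 0.00747 to 0.0279). These 4 stood at -0.05, -0.07, -0.18 and -0.28 after the GC and length correction and were not called (limma adjusted p = 0.0609 to 0.756). Among 7 blood genes Hba-a2 rose and 6 did not pass, with 5 higher adjusted over the list alone. The list had a camera adjusted p of 0.0187 (6.79e-07 to 0.494 over its alternatives), and adjusted p = 0.494 with an estimated correlation. The haemoglobin gene Hbb-bs was at 426, 635 and 4687 scaled FPKM in wild type males and at 2477 to 6867 in mutant males, and its value of 1.99 did not pass (limma adjusted p = 0.11), nor did Hbb-bt at 2.40 and the haem enzyme Alas2 at 2.16 (adjusted p = 0.0636 and 0.0694).

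The prostate bud, Müllerian, Wolffian and Wnt lists were called toward higher values in mutant males. Of 25 prostate bud and androgen genes 6 rose and 2 fell, with 8 and 2 adjusted over the list alone, among them Krt5, Bmp7 at 0.77 and Sox9 at 0.72 (limma adjusted p = 0.0147 and 0.00902), while Zbtb16 at 0.64 did not pass (adjusted p = 0.0777). Camera gave an adjusted p of 0.0348 for this list (0.0019 to 0.494 over its alternatives), and adjusted p = 0.494 with an estimated correlation. Of 15 Müllerian duct and vagina genes 3 rose, Wnt4 by 0.68, Wnt9b by 0.58 and Hoxa11 by 0.55 (limma adjusted p = 0.0388, 0.0138 and 0.0225), and Pax8 at 0.62 did not pass (adjusted p = 0.164). Wnt9b was at 0.0201 to 0.066 scaled FPKM in the female libraries, which kept the vagina, so its rise does not point to Müllerian tissue. Of 10 Wolffian duct and seminal vesicle genes 3 rose, among them the transcription factor Gata3 by 0.48 (limma adjusted p = 0.0128). Both lists had a camera adjusted p of 0.0203, with 3 members each adjusted over the list alone. Their alternatives gave 0.000474 to 0.494 and 0.0019 to 0.435, with adjusted p = 0.494 and adjusted p = 0.435 with an estimated correlation. Of 26 Wnt genes 5 rose and 0 fell, both over all genes and adjusted over the list alone, among them Wnt16, Sp5 by 0.69 and Wnt4, with Lef1 at 0.70 not passing (limma adjusted p = 0.046, 0.0388 and 0.0815 for the last 3). This list had a camera adjusted p of 0.0248 (0.00298 to 0.494 over its alternatives) and adjusted p = 0.494 with an estimated correlation. Wnt4 is on the Müllerian and Wnt lists, Wnt9b on the Müllerian and Wolffian lists, and Hoxa11 also on the list of other posterior Hox genes. The calls of these lists are therefore not separate findings.

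These list calls in males ended under several settings. The prostate bud list was lost without mutant male 1 or wild type male 2 (camera adjusted p = 0.0659 and 0.0759), and with the stricter filter it, the blood, Müllerian, Wolffian and Wnt lists were lost. The calls of Isg20, Ndufa4l2, Ppp1r1b, Bmp7, Wnt4, Wnt9b, Hoxa11, Sp5 and Ndufa1 were each lost without any 1 of at least 3 libraries. That of Gata3 was lost without mutant male 1 (limma adjusted p = 0.0568). Of the 41 named and called genes in males, 24 kept their call after the GC and length correction. Among those that did not, Isg20 went to 1.41, Ndufa4l2 to 1.31, Ppp1r1b to 1.12, Aspn to -0.68, Bmp7 to 0.61, Wnt4 and Hoxa11 to 0.49, Wnt9b to 0.37 and Sp5 to 0.47 (limma adjusted p = 0.073 to 0.251). Ddx3y and Uty went to -0.3 and -0.57 and were not called, and Eif2s3y to -0.57 and was (limma adjusted p = 0.152, 0.0642 and 0.0309). With the correction camera still called the skeletal muscle, mitochondrial, blood, Müllerian, Wolffian, Wnt and prostate bud lists (adjusted p = 4.05e-12 to 0.039, and 0.359 to 0.481 with an estimated correlation). Among single members the correction left 10 skeletal muscle and 2 mitochondrial genes lower, 0 Müllerian, 1 Wolffian and 1 Wnt gene higher, and 3 prostate bud genes higher and 1 lower. The other 19 lists were not called in males without it, while with it camera called the immune list lower and the BMP and FGF list higher (adjusted p = 0.0137 and 0.0287, and adjusted p = 0.481 with an estimated correlation for both), and the median and mean of the mesenchyme, endothelium and extracellular matrix lists differed in sign.

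In females, the largest called rises included basal keratins, histones and Ramp3, and the largest falls included Hoxd12, Hoxd13, Scg5, Idi1, Agtr2 and Ogn. Ramp3 rose from 2.06 ± 0.174 to 15.1 ± 4.50 scaled FPKM (SD, n = 3), a log2 fold change of 2.57 (SE 0.22, limma adjusted p = 0.000352). Krt5 rose from 35.9 ± 6.76 to 117 ± 38.7 (1.64, SE 0.31, adjusted p = 0.0033) and Krt17, another basal keratin, by 1.40 (adjusted p = 0.0179). The histone genes H2ac13, H3c10 and H4c9 rose by 1.94, 1.89 and 1.85, the ribosomal protein gene Rps16 by 1.73 and Rtl1 by 1.71 (limma adjusted p = 0.000118 to 0.0174). Scg5, a chaperone of neuroendocrine secretory granules, fell from 14 ± 1.78 to 2.83 ± 2.04 (-2.41, SE 0.49, adjusted p = 0.00501). It was at 4.357, 3.615 and 0.511 scaled FPKM in mutant females 1, 2 and 3. Idi1, an enzyme of cholesterol synthesis, fell by 2.03 and Agtr2, the angiotensin type 2 receptor, by 1.73 (adjusted p = 0.00102 and 0.00109).

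The matrix proteoglycan gene Ogn fell in females from 63.6 ± 1.46 to 19.7 ± 5.47 scaled FPKM (-1.70, SE 0.23, limma adjusted p = 0.000925). Klhl4, Zfp942, Depdc1a and Arhgap5 fell by 2.04, 1.70, 1.68 and 1.65. After the GC and length correction Ogn stood at -1.04, Zfp942 at -1.10, Depdc1a at -0.97 and Arhgap5 at -0.91, all 4 still called (limma adjusted p = 0.00396 to 0.0457). C1s1, a complement protease gene, was listed at 0, 0 and 0.0114 in wild type females and stood at 2.79, 3.06 and 2.89 in mutant females, so no fold is given (adjusted p = 0.000516). The mitochondrial tRNA synthetase gene Lars2 was at 29.5, 2.97 and 79.6 in mutant females and at 2.11 to 2.73 in wild type females (2.78, SE 0.87, adjusted p = 0.0352), a call lost without any 1 of 5 female libraries. Of 13904 genes, 1687 rose and 2208 fell (limma adjusted p under 0.05), 96 and 207 of them by at least 2-fold. Scaling to the library sums, which shifted the median of all genes to -0.21, gave 320 and 4038, and the FPKM as deposited gave 231 and 1435. The total of 3895 became 2439 without wild type female 1, 2400 with only the female libraries in the fit and 1090 after the GC and length correction.

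Camera called the urothelium and immediate early lists in females. Of 22 urothelium genes 7 rose and 0 fell, with 7 adjusted over the list alone, at a median of 0.55. At the preset correlation its camera adjusted p was 0.00882 (6.07e-06 to 0.809 over its alternatives), and adjusted p = 0.809 with an estimated correlation. Krt5, the keratin Krt14 at 1.08, the adhesion gene Cdh1 at 0.98 and the epithelial transcription factor Grhl3 at 0.90 led it (limma adjusted p = 0.00709, 0.0108 and 0.0378 for the last 3). Of 13 immediate early genes 5 rose and 0 fell, with 5 adjusted over the list alone. For the whole list the camera adjusted p was 0.00882 (0.000376 to 0.749 over its alternatives), and adjusted p = 0.749 with an estimated correlation. Junb rose by 0.99, Zfp36 by 0.66, Klf4 by 0.65 and Ier2 by 0.52 (limma adjusted p = 0.0032, 0.00532, 0.0136 and 0.0309); these genes respond within minutes to stimulation. The urothelium call was lost without mutant female 1 or wild type female 2 (camera adjusted p = 0.121 and 0.0944). Krt17 was at 191, 56 and 81.6 scaled FPKM in mutant females 1, 2 and 3, and its rise was 0.90 without mutant female 1. The call of Krt17 was lost without wild type female 3 and that of Klf4 without wild type female 1 (limma adjusted p = 0.0579 and 0.0527), and those of H4c9, Grhl3 and Ier2 without any 1 of at least 3 libraries. After the GC and length correction 25 of the 32 named and called genes in females kept their call. Among those that did not, Lars2 went to 2.71, Krt17 to 1.13, Grhl3 to 0.81, Junb to 0.64, Klf4 to 0.47 and Ier2 to 0.2 (limma adjusted p = 0.0602 to 0.424). Camera still called the urothelium and immediate early lists with the correction, at medians of 0.35 and 0.22 (adjusted p = 0.0109 and 0.0301, and adjusted p = 0.879 with an estimated correlation for both). Among single members the correction left 5 urothelium genes and 1 immediate early gene higher. The other 24 lists were not called in females without it, while with it camera called the skeletal muscle and neural lists lower, at medians of -0.28 and -0.71 with 0 members called (adjusted p = 0.0126 and 0.0109, and adjusted p = 0.879 with an estimated correlation for both), and the median and mean of the mesenchyme list differed in sign. In neural genes mutant female 3 lay far below mutant females 1 and 2, as given below.

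Over both sexes, with 6 libraries against 6, the largest called rises were Ramp3 at 2.11 (SE 0.16, limma adjusted p = 3.69e-05), H3c10 at 1.88, Rtl1 at 1.77 (SE 0.08, adjusted p = 1.9e-06), H2ac13 at 1.59, Krt5 at 1.54 (SE 0.22, adjusted p = 0.000329), Rps16 at 1.41, C1qtnf9 at 1.21 and Hoxd11. Spint2, an epithelial protease inhibitor, rose by 1.11 and Nrtn, a neurotrophic factor, by 1.10 (adjusted p = 0.000393 and 7.89e-05). Besides Hoxd12 and Hoxd13, the largest falls were Scg5 at -1.85 (SE 0.35, adjusted p = 0.00171), Klhl4 at -1.77 and Idi1 at -1.61 (SE 0.20, adjusted p = 0.000203). The choline transporter Slc5a7 of cholinergic neurons fell by 1.44 and the synaptic gene Syt4 by 1.42 (adjusted p = 0.00607 and 0.0276). In mutant female 3 they were at 0.22 and 0.268 scaled FPKM, against 2.05 and 3.63 and 5.03 and 7.67 in mutant females 1 and 2, and without it their values were -1.08 and -0.90. Aplnr, the apelin receptor, fell by 1.44, and Arhgap5 and Zfp942 by 1.43 and 1.42 (adjusted p = 0.000589, 9.56e-05 and 0.000316). The GC and length correction brought Arhgap5 to -0.83, Zfp942 to -0.88 and Nrtn to 0.63, all 3 still called (limma adjusted p = 0.000463, 0.00491 and 0.00286).

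Of 13904 genes over both sexes, 2631 rose and 3008 fell (limma adjusted p under 0.05), 44 and 137 of them by at least 2-fold. Males and females shared 707 of the genes that rose and 1210 of those that fell, where 146 and 257 would be shared if the calls were independent, and 4 genes were called in opposite directions. The split became 552 and 2872 with the FPKM as deposited, which shifted the median of all genes to -0.11, and 824 and 4617 with scaling to the library sums, which shifted it to -0.15. After the GC and length correction 2421 genes were called, 1195 higher and 1226 lower, of which 1771 had been called in the same direction before and 35 in the opposite one. In females 6 genes were called in opposite directions before and after it, and in males 0.

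**Figure D2:**
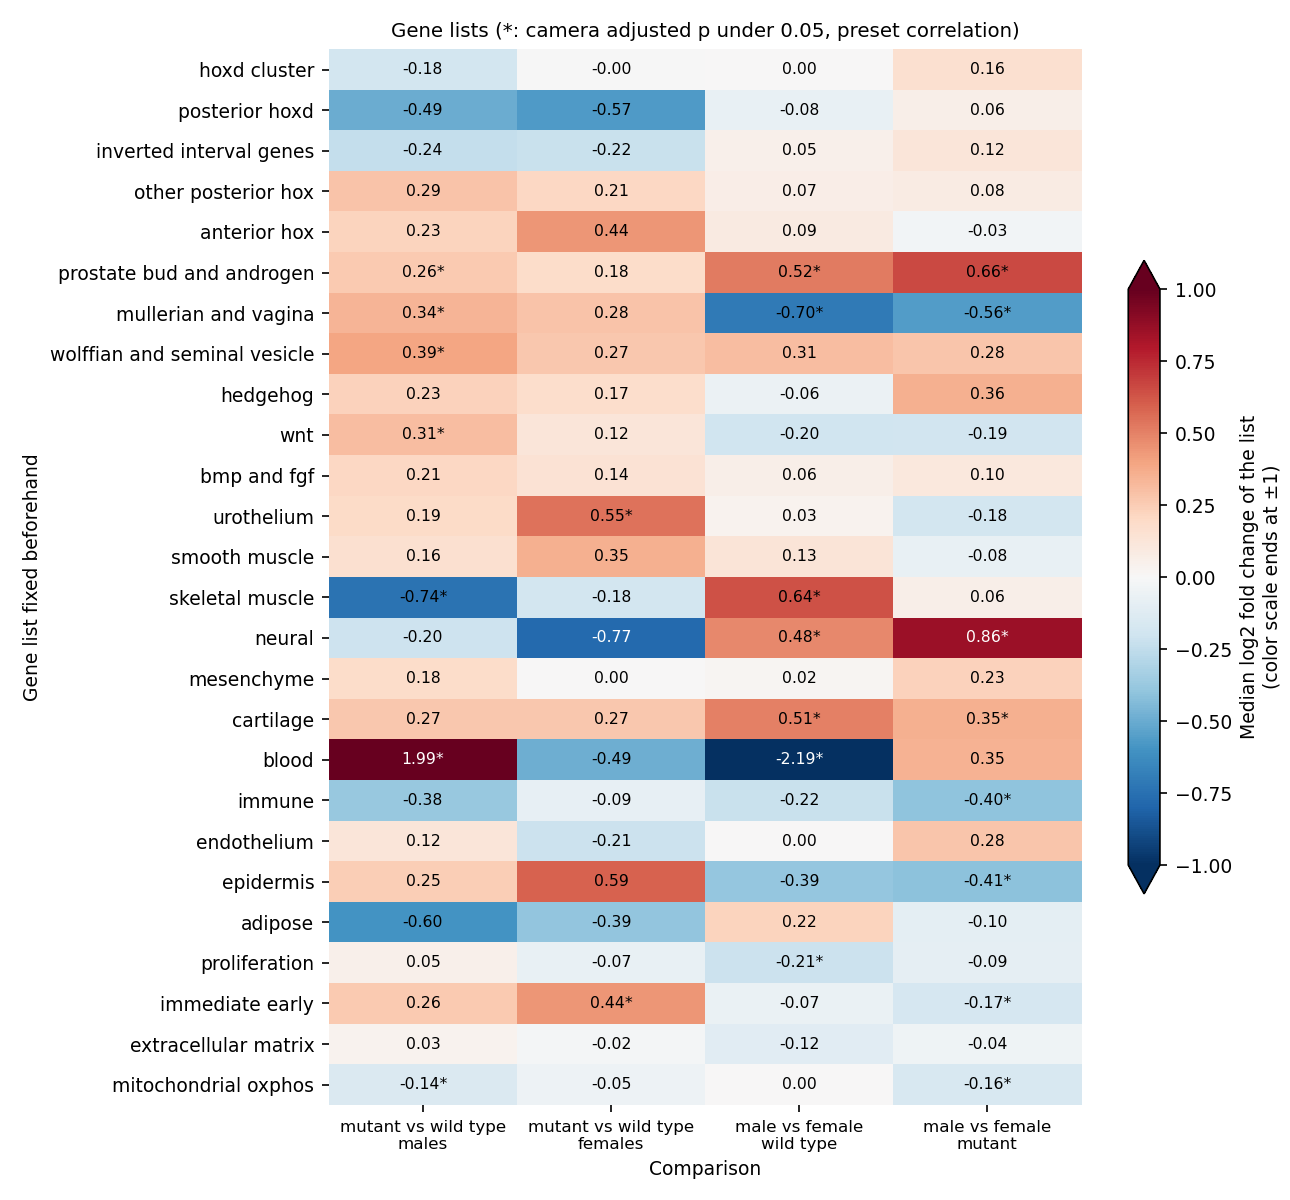
Median log2 fold change of the tested members of each of the 26 gene lists (vertical axis) in 4 comparisons (horizontal axis), in colour, with a star where the camera adjusted p was under 0.05 at the preset correlation. Skeletal muscle genes have a median of -0.74 in mutant against wild type males and 0.64 in wild type males against wild type females.

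Camera called 4 lists over both sexes. Of 24 skeletal muscle genes 14 fell and 0 rose, over all genes and adjusted over the list alone. Its camera adjusted p was 0.00779 (8.28e-08 to 0.705 over its alternatives), and adjusted p = 0.705 with an estimated correlation, led by Ckm at -1.25, Tnni2 at -0.82, and the myosins Myl1 at -0.77 and Myh8 at -0.75 (limma adjusted p = 0.000236, 0.000845, 0.00234 and 0.00228). Of 22 urothelium genes 9 rose and 0 fell, over all genes and adjusted over the list alone. Camera gave this list an adjusted p of 0.0291 (0.000409 to 0.705 over its alternatives), and adjusted p = 0.705 with an estimated correlation, with Cdh1 at 0.93 and Krt14 at 0.76 after Krt5 and Krt13 at 0.69 not passing (limma adjusted p = 0.00126, 0.00418 and 0.178). Of 15 Müllerian duct and vagina genes 7 rose and 0 fell, over all genes and adjusted over the list alone. The list had a camera adjusted p of 0.0291 (0.000133 to 0.705 over its alternatives), and adjusted p = 0.705 with an estimated correlation, with Pax8 at 0.68, Wnt7a at 0.67, Wnt4 at 0.60 and Runx1 at 0.55 (limma adjusted p = 0.024, 0.0129, 0.00678 and 0.00585). Of 13 immediate early genes 7 rose and 0 fell, with 8 adjusted over the list alone. At the preset correlation its camera adjusted p was 0.0228 (0.0016 to 0.705 over its alternatives), and adjusted p = 0.705 with an estimated correlation, with Junb at 0.61, Zfp36 at 0.57, Jun at 0.55 and Ier2 at 0.49 (limma adjusted p = 0.00367, 0.000911, 0.00036 and 0.00489). The Müllerian list was lost without mutant female 3, mutant male 1 or wild type male 2 (camera adjusted p = 0.0556, 0.0649 and 0.0559) and the urothelium list without mutant female 1, mutant male 1, wild type female 2 or wild type male 2 (camera adjusted p = 0.0812, 0.09, 0.0616 and 0.0559). After the GC and length correction camera still called the skeletal muscle, urothelium, Müllerian and immediate early lists (adjusted p = 8.28e-08, 0.0336, 0.0336 and 0.0388, and adjusted p = 0.69 with an estimated correlation for all 4). Among single members the correction left 13 skeletal muscle genes lower and 5 urothelium, 2 Müllerian and 2 immediate early genes higher. Of the 38 named and called genes over both sexes 31 kept their call after it. Besides Lnpk, those that did not were Syt4 at -1.05, Pax8 at 0.66, Wnt7a at 0.49, Wnt4 at 0.40, Junb at 0.32 and Ier2 at 0.24 (limma adjusted p = 0.0505 to 0.131). Syt4 and Pax8 also lost theirs without any 1 of 5 and 4 libraries.

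The other 22 lists were not called over both sexes. Of all genes tested, 40.6% were called in this comparison, the share against which the counts below stand. Among genes of development, 10 rose and 2 fell of 25 prostate bud and androgen genes, 5 rose and 0 fell of 10 Wolffian duct and seminal vesicle genes, 3 rose and 0 fell of 13 hedgehog genes, 10 rose and 3 fell of 26 Wnt genes, and 6 rose and 3 fell of 21 BMP and FGF genes. Of 6 posterior HoxD genes 2 rose and 3 fell. Among markers of cell types, 2 rose and 1 fell of 16 smooth muscle genes, 1 rose and 4 fell of 20 neural genes, 1 rose and 4 fell of 18 mesenchyme genes, and 3 rose and 0 fell of 8 cartilage genes. Of 7 blood, 14 immune, 12 endothelium, 9 epidermis and 5 adipose genes, 1, 0, 0, 2 and 0 rose and 0, 3, 1, 0 and 0 fell. Of 20 proliferation genes 3 rose and 5 fell, of 24 extracellular matrix genes 0 rose and 3 fell, and of 20 mitochondrial oxidative phosphorylation genes 0 rose and 6 fell. Adjusted over the list alone, the counts were the same except for hedgehog at 1 higher, neural at 0 higher and 2 lower, and immune at 2 lower. The GC and length correction left 4 higher and 2 lower in the prostate bud list, 2 and 0 in the Wolffian, 0 and 0 in the hedgehog, 3 and 2 in the Wnt, 5 and 0 in the BMP and FGF, and 0 and 0 in the neural list. With it the neural and immune lists were called lower by camera (adjusted p = 0.0388 for both, and adjusted p = 0.69 with an estimated correlation). No neural gene passed with it, and mutant female 3 lay far below mutant females 1 and 2 in neural genes, with Snap25 at 1.12 scaled FPKM against 9.75 and 15.5. The mesenchyme and extracellular matrix lists had a median and mean of different sign. Few transcripts of neighbouring organs passed the filter: 1 of 15 intestine markers, 3 of 10 kidney markers, and 0 of 14 gonad and adrenal markers, a filter count that carries no test.

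The fold changes between genotypes followed the GC content of the transcripts. Across genes, the Spearman correlation of the log2 fold change with GC content was 0.584 in males, 0.651 in females and 0.669 over both sexes, against -0.07 between the sexes in wild type and -0.27 in mutants. In males the 1374 genes of lowest GC content, around 39.6%, had a median log2 fold change of -0.38. The correction brought these correlations to 0.067, 0.010 and 0.041. Of the genes called in males, in females and over both sexes, 16.8%, 21.1% and 31.7% were still called in the same direction after it. Of those called between the sexes, 95.7% in wild type and 63.7% in mutants were. Genes over both sexes that lost their call went from a median absolute log2 fold change of 0.34 to 0.12, with a median standard error of 0.08 before and after. Their selection for no longer passing requires such a decrease.

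**Figure D3:**
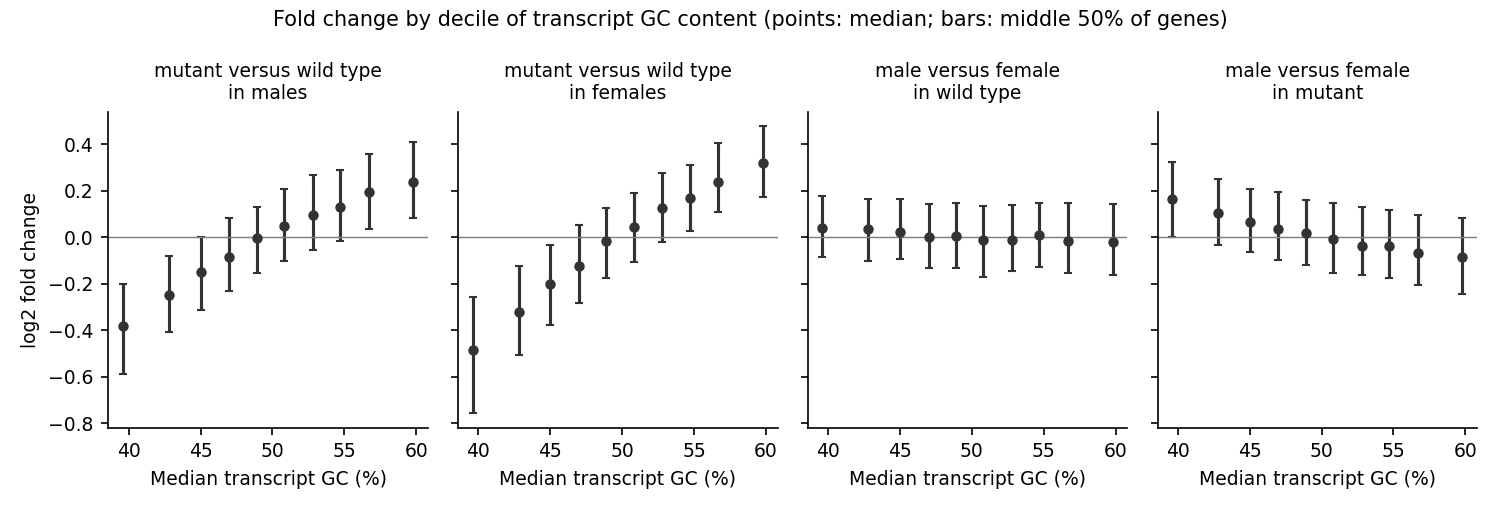
Median log2 fold change (points) and middle 50% of genes (bars) in 10 bins of transcript GC content in percent, for mutant against wild type in males and females and for male against female in wild type and mutant. Fold changes between genotypes rise with GC content, with a Spearman correlation across genes of 0.584 in males and 0.651 in females.

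Whether the mutant effect differed between the sexes was tested by the interaction. For single genes limma called 0 of 13904, with 1225 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.0908. That value belonged to C1s1, at 8.58, 4.45 and 2.50 scaled FPKM in wild type males and 2.34, 3.50 and 2.2 in mutant males, beside the female values given above. The next 4 were Bod1l at 0.57, the muscle growth inhibitor Mstn at -1.88, the proliferation marker Mki67 at 0.72 and the chromatin gene Bptf at 0.53 for the male minus the female change (limma adjusted p = 0.183 for Bod1l and 0.295 for the others), and none of these 5 passed. Leaving out wild type male 1 or wild type male 3 gave 1 call.

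Among gene lists, camera called 4 for this difference. Skeletal muscle genes were lower in mutants by more in males than in females, with a median difference of -0.60 over 24 genes. Its camera adjusted p was 1.86e-07 (2.3e-13 to 0.78 over its alternatives), and adjusted p = 0.78 with an estimated correlation. Ckm stood at -1.60, Tnnt3 at -0.89, Mybpc1 at -0.89 and Tnnc2 at -0.87, none of them called alone over all genes (limma adjusted p = 0.475 to 0.545), while 5 members were lower adjusted over the list alone. Blood genes had a median difference of 2.62 over 7 genes. For the whole list the camera adjusted p was 7.18e-05 (1.34e-12 to 0.78 over its alternatives), and adjusted p = 0.78 with an estimated correlation, with Hba-a2 at 3.89, Hbb-bt at 2.88, Alas2 at 2.68 and Hbb-bs at 2.62 and 0 members passing either way. Proliferation genes had a median of 0.16 over 20 genes. Its camera adjusted p was 0.00662 (0.000302 to 0.78 over its alternatives), and adjusted p = 0.78 with an estimated correlation, with 3 members higher adjusted over the list alone and Mki67 followed by Bub1 at 0.48, Top2a at 0.43 and Rrm2 at 0.29 (limma adjusted p = 0.295 to 0.626). Mitochondrial oxidative phosphorylation genes had a median of -0.15 over 20 genes. Camera gave this list an adjusted p of 0.000445 (1.58e-05 to 0.78 over its alternatives), and adjusted p = 0.78 with an estimated correlation, with 2 lower adjusted over the list alone and Ndufa2 at -0.36, Ndufv1 at -0.34, Uqcrfs1 at -0.32 and Cox4i1 at -0.28 (limma adjusted p = 0.538 to 0.584). The proliferation call was lost without mutant male 2 (camera adjusted p = 0.0684) and the mitochondrial call with quantile normalization (camera adjusted p = 0.0936), and the median and mean of the BMP and FGF list differed in sign. The GC and length correction kept the 4 calls at medians of -0.50, 2.74, 0.11 and -0.06 (camera adjusted p = 1.39e-06, 1.26e-05, 0.00552 and 0.0301, and adjusted p = 0.777 with an estimated correlation for all 4).

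The wild type sexes were compared next. Since the female samples kept the vagina, sex differences here and in mutants cannot be told apart from the tissue that the samples held. Wild type males had more of the retinoic acid enzyme Aldh1a1, at 27.4 ± 7.12 scaled FPKM against 2.63 ± 0.512 in wild type females (SD, n = 3; log2 3.14, SE 0.23, limma adjusted p = 3.24e-05), and of the oestrogen sulphotransferase Sult1e1, at 4.88 ± 1.12 against 0.213 ± 0.129 (2.91, SE 0.25, adjusted p = 9.48e-05). Wild type females had more of Wnt7a, a signal of the Müllerian duct epithelium, at 7.91 ± 0.667 against 0.0460 ± 0.0254 (-3.94, SE 0.26, adjusted p = 1.14e-05) and of the oestrogen receptor Esr1, at 21.8 ± 1.2 against 1.75 ± 0.0834 (-3.31, SE 0.14, adjusted p = 3.87e-07). Dsc3, Krt13 and Krt6a were also higher in females, at -3.28, -3.20 and -2.92 (adjusted p = 8.49e-06, 0.00989 and 0.00603).

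Other genes higher in wild type males were the Y-linked Ddx3y, Eif2s3y, Uty and Kdm5d, Cnmd at 2.46, a regulator of cartilage and vessels (limma adjusted p = 1.77e-06), the matrix protease Mmp7 at 3.14 (SE 0.71, adjusted p = 0.038) and C1s1 (adjusted p = 0.000179), whose wild type female values are given above. Mmp7 was at 9.21, 0.383 and 0.311 in the mutant females, and its call was lost without any 1 of 9 libraries. Further genes higher in wild type females were Xist, Dlx6os1 at -3.55, Tmem213 at -2.83, the retinoic acid binding gene Crabp1 at -2.76 and Pnliprp1 at -2.75 (adjusted p = 1.77e-06, 5.9e-05, 0.000335, 2.12e-05 and 0.00346). Of 13904 genes, limma called 271 higher and 171 lower in wild type males, 98 and 64 of them by at least 2-fold. The total of 442 depended on single libraries and settings: it was 160, 181 and 254 without wild type females 1, 2 and 3, 211 and 164 without wild type males 1 and 2, 990 and 672 without mutant females 1 and 3, 243 with the stricter filter, 254 with the FPKM as deposited, 1233 with only the wild type libraries in the fit and 3997 with library weights.

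Camera called 7 lists between the wild type sexes. Of 25 prostate bud and androgen genes 5 were higher in males and 0 lower, with 13 and 1 adjusted over the list alone. Camera gave this list an adjusted p of 1.39e-07 (2.3e-09 to 0.245 over its alternatives), and adjusted p = 0.245 with an estimated correlation. Among them were the Wnt inhibitor Wif1 at 2.32 and the androgen-responsive Zbtb16 at 1.55, while the 5-alpha-reductase Srd5a2 at 1.34 did not pass (limma adjusted p = 3.68e-05, 0.00506 and 0.102). Of 15 Müllerian duct and vagina genes 5 were lower in males and 1 higher, with 7 and 1 adjusted over the list alone (camera adjusted p = 0.000945, 2.28e-07 to 0.351 over its alternatives, and adjusted p = 0.351 with an estimated correlation). Besides Wnt7a and Esr1 these included the anti-Müllerian hormone receptor Amhr2 at -2.05 and the progesterone receptor Pgr at -1.56 (limma adjusted p = 0.00736 and 0.00149). Of 24 skeletal muscle genes 6 were higher in males and 0 lower, with 14 adjusted over the list alone. The list had a camera adjusted p of 1.01e-08 (4.17e-15 to 0.361 over its alternatives), and adjusted p = 0.361 with an estimated correlation, with Tnnt3 at 1.19, Myh8 at 1.18, Tnnc2 at 1.11 and Tnni2 at 0.94 (limma adjusted p = 0.0131, 0.0111, 0.00878 and 0.0253).

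Of 8 cartilage genes 2 were higher in wild type males, Cnmd and the collagen Col9a3 at 0.74, both over all genes and adjusted over the list alone, while Col2a1 and Acan at 0.69 each did not pass (limma adjusted p = 0.0146, 0.276 and 0.606). Camera gave this list an adjusted p of 0.0371 (0.00209 to 0.361 over its alternatives), and adjusted p = 0.361 with an estimated correlation. None of 20 neural genes passed either way (limma, 2541 of all genes at an unadjusted p under 0.05), and the list was called higher in males. At the preset correlation its camera adjusted p was 0.0358 (2.7e-06 to 0.808 over its alternatives), and adjusted p = 0.808 with an estimated correlation, with Elavl4 at 0.73, Snap25 at 0.70 and Uchl1 at 0.59 (limma adjusted p = 0.273 to 0.586). Of 20 proliferation genes 2 were lower in males, with 9 adjusted over the list alone. The list had a camera adjusted p of 2.18e-06 (5.59e-10 to 0.245 over its alternatives), and adjusted p = 0.245 with an estimated correlation. These 2 were Mki67 at -0.36 and Aurka at -0.33, with Top2a at -0.33 and Mcm5 at -0.32 not passing (limma adjusted p = 0.0489, 0.0444, 0.0537 and 0.0891). All 7 blood genes were lower in males adjusted over the list alone and none over all genes. For the whole list the camera adjusted p was 0.000162 (2.94e-10 to 0.361 over its alternatives), and adjusted p = 0.361 with an estimated correlation, with Hba-a2 at -3.22, Hbb-bt at -2.55, Hbb-bs at -2.27 and Alas2 at -2.19 (limma adjusted p = 0.115 to 0.179). The cartilage and neural calls were lost in 9 of 26 and 5 of 27 alternatives. The call of Krt13 was lost without wild type female 1 or wild type male 2, and those of Tnnt3 and Myh8 without wild type female 2 or wild type male 2 (limma adjusted p of up to 0.057, 0.0694 and 0.0609). Without wild type male 2 that of Tnnc2 was lost (limma adjusted p = 0.0519), and those of Tnni2, Col9a3, Aurka and Mki67 without any 1 of at least 3 libraries. The posterior HoxD, hedgehog and Wnt lists had a median and mean of different sign.

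In mutants, males had more of Wif1, at 10.2 ± 1.75 scaled FPKM against 1.24 ± 0.466 in mutant females (SD, n = 3; log2 2.65, SE 0.17, limma adjusted p = 9.14e-06). The androgen-responsive cochaperone Fkbp5 was higher by 1.99 and Srd5a2 by 1.87 (adjusted p = 1.42e-06 and 0.0195). Of 25 prostate bud and androgen genes 10 were higher in mutant males and 0 lower, with 16 and 1 adjusted over the list alone. At the preset correlation its camera adjusted p was 2.56e-07 (2.09e-10 to 0.395 over its alternatives), and adjusted p = 0.395 with an estimated correlation. Of 15 Müllerian duct and vagina genes 6 were lower and 1 higher, with 6 and 2 adjusted over the list alone. For the whole list the camera adjusted p was 0.00658 (8.21e-06 to 0.395 over its alternatives), and adjusted p = 0.395 with an estimated correlation. Wnt7a stood at -4.31, Esr1 at -3.16, Amhr2 at -2.52 and Pgr at -1.46 (limma adjusted p = 4.92e-06, 4.72e-07, 0.00153 and 0.00153).

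The epidermis, immediate early, immune and mitochondrial lists were lower in mutant males than in mutant females. Of 9 epidermis genes 2 were lower, Krt6a at -3.52 and Krtdap at -2.08, with 3 adjusted over the list alone, and Ivl at -0.88 and Sbsn at -0.60 did not pass (limma adjusted p = 0.00138, 0.021, 0.334 and 0.0709). Ivl was at 22.9 scaled FPKM in mutant female 1 against 7.15 and 6.86 in mutant females 2 and 3, and without mutant female 1 Ivl and Sbsn stood at -0.33 and -0.36. The list had a camera adjusted p of 0.0401 (0.000637 to 0.454 over its alternatives), and adjusted p = 0.454 with an estimated correlation. Of 13 immediate early genes 3 were lower, over all genes and adjusted over the list alone, Fos at -1.06, Junb at -0.85 and Klf4 at -0.60, and Ier3 at -0.31 did not pass (limma adjusted p = 0.041, 0.0215, 0.048 and 0.393). At the preset correlation its camera adjusted p was 0.0401 (0.0091 to 0.574 over its alternatives), and adjusted p = 0.574 with an estimated correlation. Of 14 immune genes the complement gene C1qa was lower at -0.94, with 5 adjusted over the list alone, and Cd14 at -1.32, Lyz2 at -0.77 and Tyrobp at -0.68 did not pass (limma adjusted p = 0.0109, 0.0528, 0.375 and 0.088). Without mutant female 1, where Lyz2 was at 27 scaled FPKM against 6.15 and 5.41 in mutant females 2 and 3, Lyz2 stood at -0.06 and Cd14 at -0.84. For the whole list the camera adjusted p was 0.0159 (0.000114 to 0.574 over its alternatives), and adjusted p = 0.574 with an estimated correlation. Of 20 mitochondrial oxidative phosphorylation genes 2 were lower, Ndufa2 at -0.28 and Ndufv1 at -0.27, with 3 adjusted over the list alone, and Uqcrc1 at -0.26 and Cox4i1 at -0.24 did not pass (limma adjusted p = 0.0325, 0.0301, 0.0531 and 0.146). Its camera adjusted p was 0.0014 (9.84e-06 to 0.722 over its alternatives), and adjusted p = 0.574 with an estimated correlation. The median of this last list turned from -0.16 to 0.02 with scaling to the library sums, and the epidermis, immediate early and mitochondrial calls were lost in 9, 7 and 5 of 27 alternatives, the GC and length correction among them. The immune call was lost without mutant female 2, mutant male 1 or mutant male 2 (camera adjusted p = 0.0978, 0.0574 and 0.0671), and the calls of Fos, Klf4, Ndufa2 and Ndufv1 without any 1 of at least 4 libraries. Those of Srd5a2, Krtdap and Junb were lost without mutant male 2 or 3, mutant male 1 or 2, and mutant male 3 (limma adjusted p of up to 0.0669, 0.0696 and 0.0512).

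Higher in mutant males were 2 of 8 cartilage genes, Cnmd at 2.92 and Col9a3 at 0.62, with 3 adjusted over the list alone, while Col2a1 at 0.91 and Col11a1 at 0.46 did not pass (limma adjusted p = 4.72e-07, 0.0244, 0.104 and 0.292). Camera gave this list an adjusted p of 0.0272 (0.00629 to 0.395 over its alternatives), and adjusted p = 0.395 with an estimated correlation. Of 20 neural genes 1 was higher, with 4 adjusted over the list alone. Its camera adjusted p was 0.000365 (1.34e-08 to 0.574 over its alternatives), and adjusted p = 0.574 with an estimated correlation, while the 4 members with the largest differences, Dbh at 1.52, Tubb3 at 1.35, Prph at 1.33 and Elavl3 at 1.24, did not pass (limma adjusted p = 0.0531 to 0.319). Tubb3 and Prph were at 5.82 and 6.18 scaled FPKM in mutant female 3, against 66.3 to 124 and 69.3 to 116 in mutant females 1 and 2, and without mutant female 3 their differences were 0.06 and 0.08 and the median of the list went from 0.86 to 0.27. Of 13904 genes, limma called 553 higher and 489 lower in mutant males, 141 and 152 of them by at least 2-fold. The total of 1042 became 516, 496 and 433 without mutant males 1, 2 and 3, 401 with the FPKM as deposited, 661 without the filter, 209 with only the mutant libraries in the fit, and 1932 with scaling to the library sums, where 1702 were higher and 230 lower and the median of all genes shifted to 0.17. The cartilage call was lost without mutant female 1 (camera adjusted p = 0.268), and the anterior Hox and Wnt lists had a median and mean of different sign, while the adipose list had a median and mean below 0 and a test above it.

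The sex differences of the 2 genotypes were compared across genes, which are not independent replicates. Over 13904 genes Pearson's r was 0.59 and Spearman's rho 0.451, and over the 418 autosomal genes called in wild type r was 0.928 and rho 0.922. Keeping only called genes keeps large differences, which by itself tends to raise the correlation. Of these 418 genes 406 (97.1%) had the same sign in mutants and 270 were called there in the same direction. Their median absolute log2 difference was 0.84 in wild type and 0.69 in mutants, where the wild type values were selected for being called. Genes called in both genotypes numbered 182 higher and 103 lower in males, where 10.8 and 6 would be shared if the calls were independent.

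**Figure D4:**
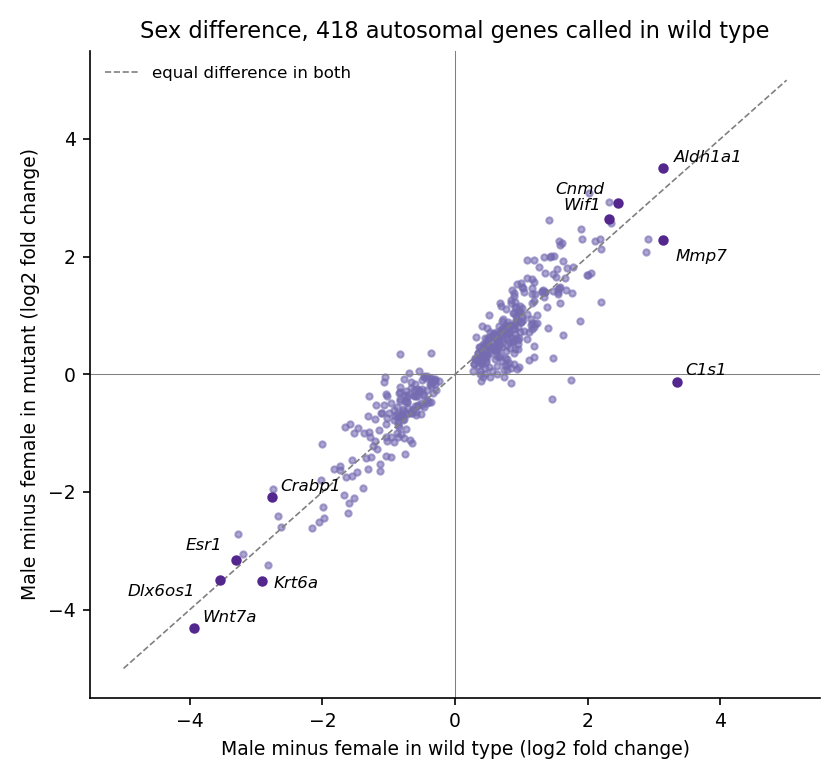
Log2 difference between males and females in wild type (horizontal axis) and in mutants (vertical axis), with a point for each of the 418 autosomal genes called in wild type. The points follow the diagonal with a Pearson correlation of 0.928, and 406 of them have the same sign on both axes. The choice of genes called in wild type by itself tends to raise this correlation.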

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

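No test was added for this part after its results were seen. Of the 9 results below, the gene lists came up by a test of the difference of the mutant effect between males and females. The single genes were the named genes whose mutant libraries all lay above the wild type libraries in one sex and all below them in the other. Each value is the log2 fold change in males minus that in females.

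Among gene lists, the difference passed by camera at the preset correlation for 4 lists and for 0 lists with an estimated correlation, where each of the 4 had an adjusted p of 0.78. The median was -0.605 for skeletal muscle genes (adjusted p = 1.86e-07), 2.617 for blood genes (adjusted p = 7.18e-05), 0.16 for proliferation genes (adjusted p = 0.00662, and 0.0684 without mutant male 2) and -0.147 for mitochondrial oxidative phosphorylation genes (adjusted p = 0.000445). Over the alternatives their adjusted p ran from 2.3e-13, 1.34e-12, 0.000302 and 1.58e-05 to 0.78. The haemoglobin gene Hbb-bs was at 4687 scaled FPKM in wild type male 3 against 426 and 635 in wild type males 1 and 2, so the blood list varied widely within a group.

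Among single genes, the values were 0.573 for Bod1l (limma adjusted p = 0.183), -1.88 for Mstn (adjusted p = 0.295), 0.722 for Mki67 (adjusted p = 0.295), 0.531 for Bptf (adjusted p = 0.295) and -0.339 for Ndufv1 (adjusted p = 0.538), and none of these 5 passed. Limma called 0 genes for this difference, with 1225 at an unadjusted p under 0.05. With a real count of 0, all 100 of the 100 splits of the libraries within sex give at least as many genes by construction, so they decide nothing about chance. The other splits were a random draw from those possible. The highest of those drawn called 1568 genes. It kept the mutant females together and set mutant male 3 with wild type males 1 and 3, so this count points to the structure by genotype.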

How the results depend on the processing

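The GC and length correction, its combination with the replicate block, protein-coding genes only and the omission of single libraries for the correlation were chosen after seeing the data. For named genes, the other alternatives kept direction and side of the threshold in 2899 cases, with 193 weaker, 54 newly past it and 17 turned, and single-library omissions in 2601, with 170, 34 and 12. For the values below the cause was not tested.

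In males, 2820 genes were called, and 1350 with the FPKM as deposited (121 higher, 1229 lower), 5991 with library weights, 556 after the GC and length correction and 450 after it with the replicate block. Omitting 1 library gave 1240 to 3948, with 1240 without mutant male 1, 1649 without mutant male 2, 1247 without wild type male 1 and 1817 without wild type male 2. In females, 3895 became 1666 as deposited (231 higher, 1435 lower), 2400 with only the groups compared, 1090 after the correction and 983 after it with the replicate block, and 2439 (without wild type female 1) to 4112 without 1 library. Over both sexes, 5639 became 3424 as deposited (552 higher, 2872 lower), 2421 after the correction and 2354 after it with the replicate block, and 4675 to 6364 without 1 library. Scaling to the library sums gave 444 higher and 1992 lower in males, 320 and 4038 in females and 824 and 4617 over both sexes.

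The difference between the sexes in the mutant effect had 0 genes called by limma (1225 at an unadjusted p under 0.05), and 1 with a pseudocount of 0.1, 8 with no filter, 1 as deposited, 1 with library weights and 0 to 1 without 1 library, with 1 without wild type male 1 or wild type male 3. Between the wild type sexes, 442 became 243 with the stricter filter, 254 as deposited, 1233 with only the groups compared and 3997 with library weights. Omitting 1 library gave 160 to 990: 990 and 672 without mutant females 1 and 3, 160, 181 and 254 without wild type females 1, 2 and 3, and 211 and 164 without wild type males 1 and 2. Between the mutant sexes, 1042 became 661 with no filter, 401 as deposited, 1932 with scaling to the library sums (1702 higher, 230 lower) and 209 with only the groups compared. Omitting 1 library gave 433 to 1369, with 516, 496 and 433 without mutant males 1, 2 and 3.

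With the replicate block alone, the counts were 2857, 3935, 5770, 0, 365 and 963 in the order of the comparisons, and 33 list calls. The replicate numbers did not pair the libraries visibly. The deviations of each library from its group mean were correlated between libraries of different groups. These correlations ran from -0.226 to 0.317 for the same number, with 3 of 18 over 0.1, and from -0.268 to 0.231 for different numbers, with 8 of 36.

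Camera called 32 lists over the 6 comparisons, 50 with no filter, 55 as deposited, 52 with scaling to the library sums, 0 with an estimated correlation and 30 to 46 without 1 library. The correlation of the sex differences, 0.59, was 0.536 with no filter, 0.656 with protein-coding genes only and 0.503 to 0.651 without 1 library.

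The named genes that turned were these. In females, Hoxd9 (-0.001) stood at 0.001 with a pseudocount of 1, 0.068 with quantile normalization and -0.171 to 0.139 without 1 library, and Hoxd8 (0.044) at -0.047 as deposited, -0.172 with scaling to the library sums, -0.061 with library weights, -0.163 after the correction with or without the replicate block, and -0.079 to 0.121 without 1 library. Hoxd8 over both sexes ran from -0.084 to 0.016 without 1 library. In males, Kdm5d stood at -0.044 as deposited and -0.037 to 0.272 without 1 library, and Hoxd3os1 at 0.03 after the correction with or without the replicate block and -0.251 to 0.077 without 1 library. Lnpk turned to 0.33 in males, 0.245 in females and 0.287 over both sexes after the correction, with or without the replicate block. Cox4i1 between the mutant sexes turned to 0.072 with quantile normalization. Depth limited all of this to relative terms, since FPKM give no counts.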

Other observations

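The 4 gene lists in this part, the comparison with other posterior Hox genes and the depth comparison of batches were chosen only after the results were seen. So were the Xist test and the comparison with other splits for the GC trend. Replication-dependent histones, made when cells copy their DNA, were higher in mutants: of 50 tested genes 28 rose and 0 fell over both sexes at a median of 0.41, with 5 rising in males and 22 in females (camera p = 2.54e-09 over both sexes, not adjusted, and p = 0.268 with an estimated correlation). After the GC and length correction 12 rose over both sexes, and 9, 25 and 8 with no scaling, quantile normalization and scaling to the library sums, with the median above 0 in each. Omitting 1 library gave 19 to 41 over both sexes, 2 to 27 in males and 7 to 30 in females, and the correction left 3 in males and 8 in females. Between the mutant sexes 14 of the 50 were lower in males and 0 higher (median -0.61, camera p = 4.28e-18, and p = 0.121 with an estimated correlation), with 33 lower without mutant female 1, 25 without wild type male 3, 13 and 10 without wild type males 1 and 2, and 1 to 8 without each of the other 8 libraries, and with 4 lower and a median of -0.327 after the correction. Between the wild type sexes limma called 0 of the 50, with 2541 of all genes at an unadjusted p under 0.05, and the median was -0.47 (camera p = 9.75e-15, and p = 0.161 with an estimated correlation). Omitting wild type male 3 gave 27 lower, and any other library 0 or 1.

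Of 76 cytosolic ribosomal protein genes 26 rose and 2 fell over both sexes (median 0.17), while quantile normalization gave 13 and 13 and turned the median to -0.01, and scaling to the library sums gave 8 and 7 and turned it to -0.003. In mutant males 37 of the 76 were lower than in mutant females (camera p = 7.17e-31, and p = 0.0773 with an estimated correlation), 49 without wild type male 3, 36 without mutant female 2, 3 to 19 without each of the other 10 libraries, 15 after the GC and length correction, and 2 or fewer with the other 3 scalings. Between the wild type sexes the median was -0.229 with 0 called (camera p = 6.28e-15, and p = 0.209 with an estimated correlation), and 5 lower without wild type male 3. Of 20 genes of cholesterol synthesis 6 fell and 0 rose in females (camera p = 0.0168, and p = 0.435 with an estimated correlation), 1 after the GC and length correction, 10 without mutant female 2, and 2, 2, 3, 3 and 4 without wild type females 1 and 2, mutant females 1 and 3 and wild type female 3. The median of the 20 in females was -0.18 before the correction and -0.19 after it (camera p = 0.00103 after it, at the preset correlation). Over both sexes 6 fell: Idi1 by 1.61, Sc5d by 0.42, Hmgcs1 by 0.42, Msmo1 by 0.40, Cyp51 by 0.34 and Sqle by 0.29, with 1 lower after the correction and 4 to 10 lower on omitting 1 library (camera p = 0.0818 with neither, and p = 0.566 with an estimated correlation). The median of this list over both sexes was -0.15, and -0.12 after the correction (camera p = 0.0144 after it, at the preset correlation). Rtl1 rose by 1.77 over both sexes (SE 0.08, limma adjusted p = 1.9e-06), and of the other 5 tested genes of its imprinted cluster Rian fell by 0.42 (adjusted p = 0.0244) and 4 did not pass. Rtl1 has an antisense partner transcript, and the strand setting was not stated. In males Dio3 of this cluster was higher, by 1.04 in wild type and 1.40 in mutants (adjusted p = 0.00272 and 0.000262).

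Of 13904 genes, 5639 differed over both sexes between mutant and wild type libraries, and fold changes followed GC content. After the GC and length correction 31.7% of the genes called over both sexes were still called in the same direction. That share fell between the bounds set in advance, 10% and 50%, so it did not decide. After the correction 2421 genes were called, against at most 348 in the 99 other splits drawn at random. Those splits mix the genotypes, so a remainder of the trend or separate handling of the libraries would also set the real split apart. The counts therefore do not decide either. For the genes that lost their call, the median absolute log2 fold change went to 0.12, 35% of the value before. Their standard errors were about equal. These genes were selected for no longer passing, which at equal standard errors requires a smaller fold change. The decrease therefore does not decide, and the trend stays an open explanation for them. Separate handling of mutant and wild type libraries cannot be told apart from genotype, since the shallowest wild type library had 1.13 times the relative depth of the deepest mutant library, and a biological effect of the genotype stays open too.

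Hoxd12 and Hoxd13 were lower and Hoxd11 higher in mutants. The GC trend is argued against by a mean of -1.914 for Hoxd12 and Hoxd13 and a value of 1.486 for Hoxd11 after the correction. A general fall of posterior Hox genes is argued against by the median of 0.158 for those of the other clusters, which lay above 0 under each of the 4 scalings. For Hoxd11, reads from the d11lac allele cannot be told apart from expression of the gene, since 0 genes of the table are named for a reporter. An effect of the inversion on genes of the cluster may be involved, as a hypothesis that these data do not test.

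Ddx3y, Eif2s3y and Uty were lower in mutant males, by a mean of -0.984. Female RNA in those libraries is argued against, since their Xist was 0.15% of that of mutant females, against 0.98% in wild type. Whether the GC trend is the cause cannot be told: the X-linked homologs Ddx3x, Eif2s3x and Kdm6a moved by a mean of -0.418, the 3 Y-linked genes by -0.479 after the correction, and Eif2s3y was still called (limma adjusted p = 0.0309). Kdm5d, richer in GC at 43.8%, had a value of 0.09. A biological effect of the genotype on these genes stays open and untested.

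Other splits of the libraries were counted for each comparison. Over both sexes 1 of 100 splits, the real one, called as many as 5639 genes, and the highest other called 1254. That other split exchanged mutant male 3 and wild type male 3. The counts argue against an arbitrary grouping of these libraries, but they do not tell genotype from separate handling. For the genotypes in males and in females and the sexes in wild type and in mutants, 10 splits are too few for a share under 0.05. The real split was the 1 with the highest count in each: 2820 against at most 1 in males, 3895 against at most 0 in females, 442 against at most 1 between the wild type sexes and 1042 against at most 1 between the mutant sexes.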
